A study of Homo sapiens with 11 samples.

How the data were processed

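Expression was measured on Affymetrix HG-U133 Plus 2.0 arrays, 11 arrays in 6 groups. Per the labels, biotinylated cRNA was made from 6 ug of total RNA that had been extracted with a Qiagen kit, and GCRMA and Partek were used in processing. Their versions are not given in the sources used here. The deposited values are log2 values, 1 per probe set and array, which the authors normalised between arrays: the mean over all 54675 probe sets was 6.07 on each array. The values ran from 2.85 to 14.9, which fits a log2 scale. All columns were used, with 0 per-sample columns left unmapped. Xenograft RNA can hold mouse RNA, which was not separated here.

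Groups were taken from the labels as wild type, first generation, RAF1 transfected, lung metastases and visceral metastases with 2 arrays each, and RAF1 first generation with 1. The labels give no batch, day or pairing. Gene symbols came from the array annotation: 41097 probe sets had exactly 1 symbol, 1801 had several and 11777 had none listed. Of the 41097, 41043 had a gene identifier in a reference gene table (assembly GRCh38.p14), and 0 symbols were changed by it. That table was used only for names and for which genes neighbour each other, so no positions are given. Per gene, the probe set with the highest mean over all arrays was kept among those with 1 symbol, which gave 19775 genes. A gene was tested when at least 2 arrays had a log2 value of 5 or more, which left 14753 genes. The 62 control probe sets of the array were used only to describe RNA quality and labelling. The level of RAF1 is not analysed here, because 0 probe sets carried that name in the annotation used.

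Group means were fitted to the log2 values with limma 3.58.1 (lmFit and eBayes, constant prior) in R 4.3.3. All 11 arrays shared 1 estimate of the spread, with 5 residual and 3.13 prior degrees of freedom. In the comparisons with RAF1 first generation, the lone array is assumed to vary like the other groups. The 8 comparisons were RAF1 transfected and first generation, each minus wild type, RAF1 first generation minus RAF1 transfected and minus first generation, lung and visceral metastases, each minus RAF1 transfected, visceral minus lung metastases, and the difference between the RAF1 effects in first-generation material and in the groups not called first generation. A RAF1 effect here means the difference between groups with and without the RAF1 label, whatever its cause. The p-values were two-sided and adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05 and no fold threshold.

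The comparisons, filters, gene lists, alternatives and the rule for named genes were chosen before the data were examined. The rule took, per comparison, the 10 largest rises and the 10 largest falls among genes past the threshold that changed by at least 1 on the log2 scale and whose groups did not overlap, with the 5 largest in each direction and no condition on overlap for the difference between effects, and up to 4 members of each list described. RAF1 itself, which the rule also names, was not used here.

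The 25 gene lists were estrogen receptor targets, ERK pathway transcripts, luminal and basal epithelial markers, epithelial junction and splicing genes, mesenchymal genes, mammary stem cell markers, cell cycle, centrosome, hypoxia, interferon-stimulated, unfolded protein and amino acid stress, cholesterol synthesis, NF-kB cytokine and TGF-beta response genes, and markers of other cell types that xenografts or metastases could hold: fibroblasts and matrix, endothelium, macrophages and leukocytes, lung epithelium, hepatocytes, gut, pancreas and kidney epithelium, mesothelium, erythroid cells, skeletal muscle and adipocytes. Of 379 list symbols, 23 had no probe set of 1 symbol. Each list was tested with camera in limma (preset correlation 0.01, two-sided), with Benjamini-Hochberg adjustment over the 25 lists of a comparison, which made 200 list and comparison pairs. Each list was also tested with an estimated correlation and with fry, and members were counted over all genes and adjusted over the list alone.

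The alternatives were no filter and a filter at a log2 value of 7, quantile normalization, centring each array on its median, the mean over all probe sets of a gene, only probe sets without suffixes for shared sequence, only the arrays compared, an intensity trend with a robust prior, array weights, a fold threshold of 1 on the log2 scale, other reference groups for the metastases, and leaving out each array in turn. Overlaps of gene lists that share control arrays were set against independent lists and against 50 simulations of unchanged groups. On simulated data with 14753 genes, 58% of genes changed by 1 and 93% of genes changed by 2 on the log2 scale were recovered for RAF1 transfected minus wild type, with 7 false calls among 158. For RAF1 first generation minus RAF1 transfected, 43% and 84% were recovered, with 3 false calls among 130. Of simulated unchanged lists, 3.02% had a camera p under 0.05 in the first of these comparisons. In all these simulations genes were drawn independently, so this rate does not cover lists whose members move together. Each gene also had the same spread in all groups. The pairs of arrays here had standard deviations of the difference from 0.149 to 0.477, so the simulated rates may not carry over. The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.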

Results

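Gene expression was measured on 11 arrays of the human breast cancer line MCF7, an estrogen receptor-positive luminal line, with or without a retrovirus that carried a constitutively active RAF1 cDNA. RAF1 is a kinase at the head of the MEK and ERK cascade. The labels put the arrays into 6 groups: wild type (2 arrays), first generation (2 arrays), RAF1 transfected (2 arrays), RAF1 first generation (1 array), lung metastases (2 arrays) and visceral metastases (2 arrays). According to the series description, RNA came from cultured cells or from xenografts in nude mice. The labels do not say which of these a group called first generation was, which cells gave the metastases, or whether the arrays of a group were separate cultures or animals. If they were not, the p-values measure only the spread between these samples, which may be technical.

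Each array gave values for 54675 probe sets, between 2.85 and 14.9 on the log2 scale, and 14753 genes were tested. The median value per array lay between 5.32 and 5.37, and between 13065 and 13804 tested genes per array had a log2 value of 5 or more. The 3 prime minus 5 prime difference of the ACTB control probe sets, a sign of RNA degradation, lay between 0.27 and 0.60 on the log2 scale. For GAPDH it lay between 0.20 and 0.33. The number of arrays limits the precision of every value, and no spread could be taken within RAF1 first generation, which had no replicate.

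The first principal component carried 55.0% of the variance and parted the 4 wild-type and first-generation arrays (scores between -62.5 and -51.1) from the 7 other arrays (scores between 28.6 and 32.7). The second component carried 14.1% and parted wild type from first generation. The standard deviation of the gene-by-gene difference within a pair of arrays was 0.157 in wild type and 0.149 in visceral metastases, on the log2 scale. It was 0.455 in first generation, 0.431 in RAF1 transfected and 0.477 in lung metastases.

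**Figure D1:**
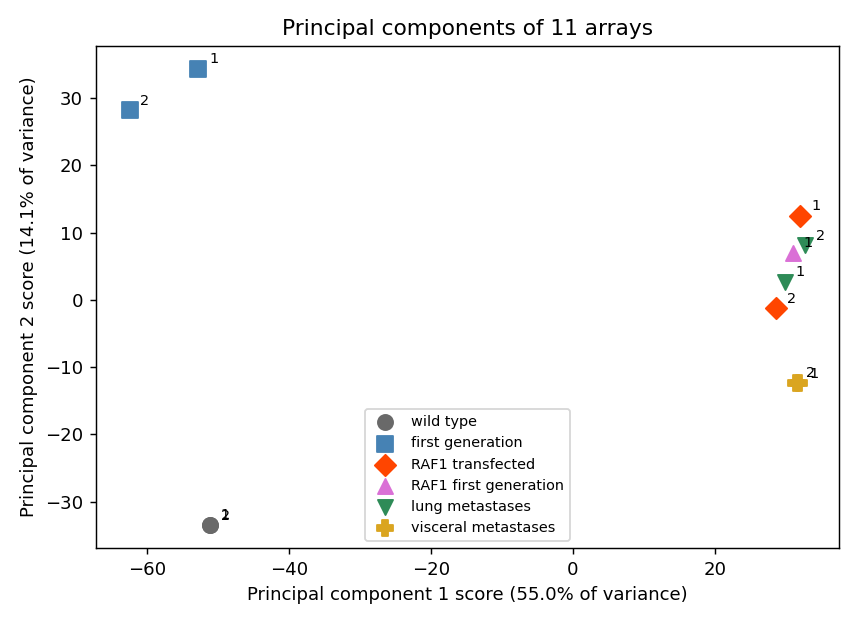
Scores of the 11 arrays on the first (55.0% of variance) and second (14.1%) principal components of the log2 values, with the replicate number beside each point. The 4 wild-type and first-generation arrays lie at negative scores of the first component and the 7 other arrays at positive scores.

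**Figure D2:**
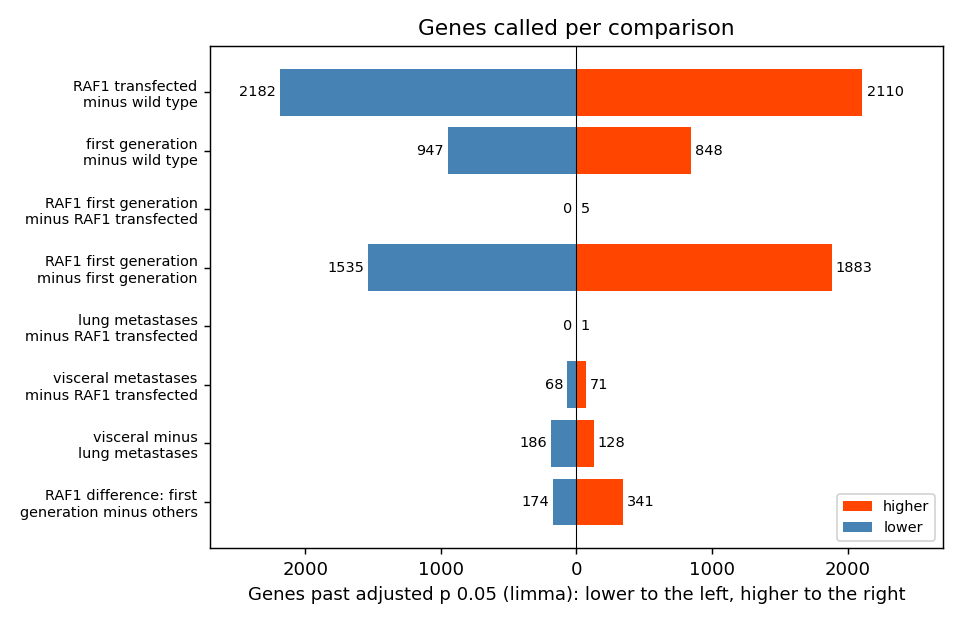
Number of genes past an adjusted p of 0.05 in each comparison (limma, 14753 genes tested), with lower genes to the left of 0 and higher genes to the right. The counts range from 1 gene for lung metastases minus RAF1 transfected to 4292 for RAF1 transfected minus wild type, and the last bar is the difference between the RAF1 effect in the first-generation groups and that in the groups not called first generation.

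RAF1-transfected cells were compared with wild-type cells, the groups not called first generation. No group was labelled as an empty-vector control and the level of RAF1 was not analysed. The differences thus cannot be assigned to the kinase itself. The largest rise was that of PLS3, an actin-bundling protein, from 4.06 ± 0.10 (SD, n = 2) to 10.79 ± 0.02 (SD, n = 2), a log2 difference of 6.73 (SE 0.15, adjusted p = 4.51e-07). WDR72 rose by 6.58 (SE 0.16), the membrane protein gene TM4SF1 by 6.46 (SE 0.71), the cytokine gene IL20 by 5.33 (SE 0.76) and the atypical cadherin gene FAT1 by 4.62 (SE 0.31). The largest fall was that of CA2, carbonic anhydrase II, from 12.09 ± 0.02 to 3.99 ± 0.06 (SD, n = 2 each), a log2 difference of -8.10 (SE 0.38, adjusted p = 9.80e-06). The files hold no detection calls, so a signal under a log2 value of 5 was not shown to lie above background, and the size of a difference against such a group may be too small. AGR2 and AGR3, protein disulfide isomerase family members common in luminal breast cells, changed by -5.98 (SE 0.49) and -5.99 (SE 0.52). PYCARD, which encodes the inflammasome adaptor ASC, changed by -5.32 (SE 0.23), the cancer-testis gene CT83 by -6.28 (SE 0.12) and the matrix Gla protein gene MGP by -5.67 (SE 0.81).

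In limma, 4292 of 14753 genes changed between RAF1 transfected and wild type at an adjusted p of 0.05, 2110 higher and 2182 lower, and 1586 of them by at least 2-fold. With each array centred on its median, 2171 were higher and 2026 lower. Of 19 measured estrogen receptor targets, 9 fell, 0 rose and 10 did not pass, and 10 fell when adjusted over the list alone. Among them PDZK1 changed by -4.64 (SE 0.22), RET by -2.42 (SE 0.57), RERG by -2.18 (SE 0.42) and ADCY9 by -1.93 (SE 0.24). The list was shifted down (camera, adjusted p = 0.000486), with an adjusted p = 0.629 with an estimated correlation. Of 7 measured basal markers 4 fell and 0 rose, also when adjusted over the list alone, with ANXA1 at -3.85 (SE 0.60) and ITGB4 at -2.23 (SE 0.20). The basal list was shifted down (adjusted p = 0.0265, and adjusted p = 0.629 with an estimated correlation). Of 14 mesenchymal genes 5 fell and 1 rose, also when adjusted over the list alone, with the matrix genes FN1 at -3.30 (SE 0.17) and TGFBI at -3.05 (SE 0.41) and the intermediate filament gene VIM at 0.98 (SE 0.15). That list too was shifted down (adjusted p = 0.0445, and adjusted p = 0.629 with an estimated correlation).

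Of 12 cholesterol synthesis genes 4 fell and 0 rose between RAF1 transfected and wild type, and 6 fell when adjusted over the list alone (list shifted down, adjusted p = 0.021, and adjusted p = 0.772 with an estimated correlation). SQLE, squalene epoxidase, was among those that fell, at -1.26 (SE 0.29). All 18 measured interferon-stimulated genes had a negative difference, with a median of -1.99, but 0 passed over all genes or adjusted over the list alone. The interferon list was called at an adjusted p = 0.0478, against an adjusted p = 0.878 with an estimated correlation. Without RAF1 transfected array 1, the adjusted p of the interferon list was 0.813. Without RAF1 transfected array 2 that of the cholesterol list was 0.179, that of the basal list 0.0738 and that of the mesenchymal list 0.0738. The mesenchymal call also ended without RAF1 transfected array 1 (0.0702), wild-type array 1 (0.0634) or either lung metastases array (0.0571). The interferon call also ended without either wild-type array (0.0634 and 0.0729) or either first-generation array (0.0651).

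ERK pathway transcripts went both ways between RAF1 transfected and wild type, with 3 of 20 higher and 6 lower, the same counts when adjusted over the list alone, a median of -0.32 and no list call (adjusted p = 0.228). EPHA4 fell by 2.75 (SE 0.60), the ERK phosphatase gene DUSP4 by 2.62 (SE 0.62) and the inhibitor gene SPRED1 by 1.90 (SE 0.20), while IER3 rose by 1.81 (SE 0.15). Luminal markers also moved apart, 4 of 15 higher and 5 lower (4 and 7 adjusted over the list alone), with SPDEF at 1.30 (SE 0.20) and ERBB3 at 1.00 (SE 0.20) against AGR2 and MLPH, the last at -1.18 (SE 0.27). The luminal list was not called (adjusted p = 0.333). Of 14 unfolded protein and amino acid stress genes, 6 rose and 2 fell, also when adjusted over the list alone, with ASNS at 2.37 (SE 0.61), ATF4 at 1.41 (SE 0.18), DDIT3 at 1.24 (SE 0.19) and VLDLR at -1.58 (SE 0.40). The stress list was not called (adjusted p = 0.331). The count of 4292 genes was 1793 without wild-type array 1 and 1866 without wild-type array 2. SYNPO2, an actin-associated protein gene at -6.20 (SE 1.40), was the single gene of the 20 named by rule that lost its call without an array, with adjusted p up to 0.0754 without wild-type array 2, 0.0723 without wild-type array 1 and 0.0592 without RAF1 transfected array 1.

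**Figure D3:**
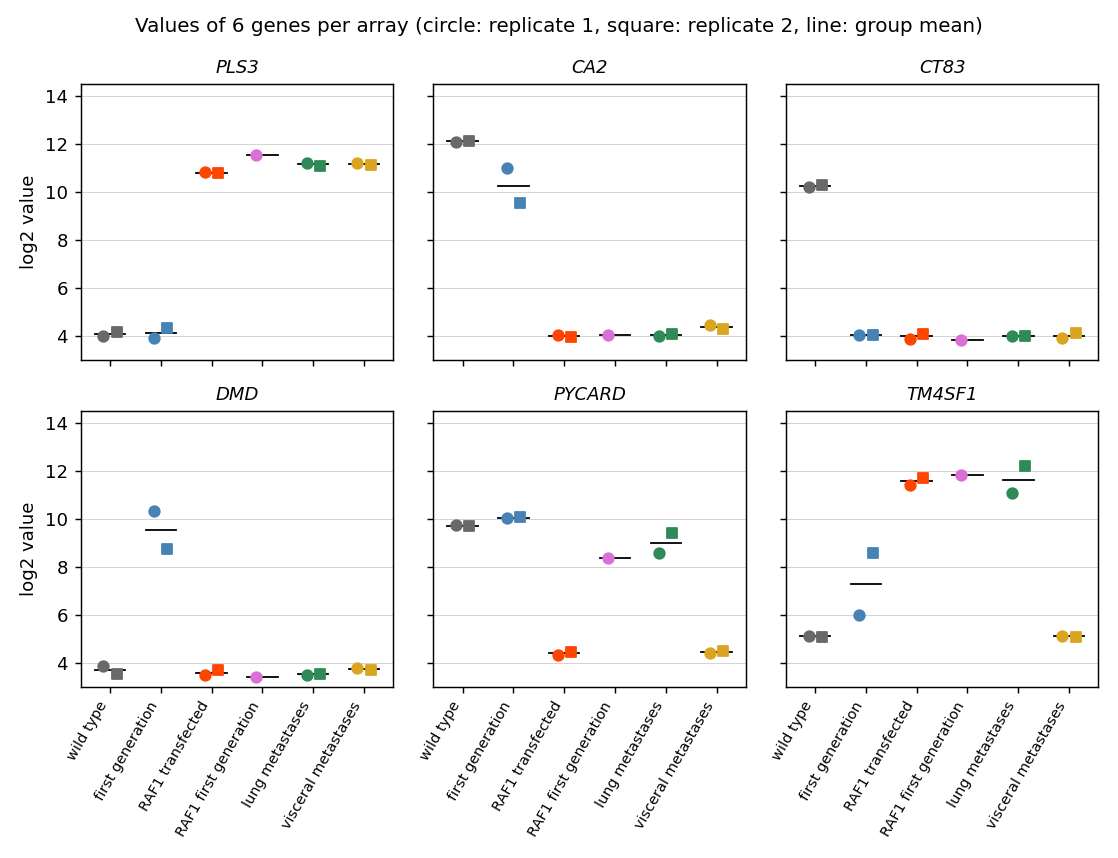
Log2 values of 6 genes on each array, by group, with the group mean as a line. PLS3 was near 4 in wild type and first generation and above 10 in the other groups, CT83 was above 10 in wild type alone, DMD was high in first generation alone, and PYCARD and TM4SF1 were low in visceral metastases (4.44 and 5.10).

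First-generation material without the RAF1 label was compared with wild type. The labels do not say that 1 of these groups came from the other or what else differed between them. The differences thus cannot be assigned to a single factor. DMD, the gene of dystrophin, rose from 3.68 ± 0.23 to 9.51 ± 1.12 (SD, n = 2 each), a log2 difference of 5.83 (SE 0.42, adjusted p = 0.000212). The angiotensin receptor gene AGTR1 rose by 5.32 (SE 0.42), the gap junction gene GJA1 by 5.05 (SE 0.50), FAT1 by 4.78 (SE 0.31) and the tissue plasminogen activator gene PLAT by 4.15 (SE 0.12). CT83 changed by -6.24 (SE 0.12), MGP by -4.89 (SE 0.81), the estrogen-responsive scaffold gene PDZK1 by -4.18 (SE 0.22) and the melanosome gene TYRP1 by -4.12 (SE 0.42). In limma, 1795 of 14753 genes changed, 848 higher and 947 lower, and 687 by at least 2-fold.

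Of 23 cell cycle genes, 7 fell and 0 rose between first generation and wild type, and 8 fell when adjusted over the list alone, with TYMS at -1.63 (SE 0.26), MCM5 at -1.51 (SE 0.18) and MCM7 at -1.43 (SE 0.20). The list was shifted down by a median of -1.08 (adjusted p = 1.63e-05, and adjusted p = 0.924 with an estimated correlation). Its median value was 9.79 on first-generation array 1 and 8.34 on array 2, and without array 2 the adjusted p of the list was 0.406. Centrosome genes followed, with 3 of 16 lower and 0 higher (5 lower adjusted over the list alone), CDK5RAP2 at -1.09 (SE 0.27) among them. Their list call (adjusted p = 0.028, and adjusted p = 0.924 with an estimated correlation) ended without first-generation array 2 (0.389) and without wild-type array 2 (0.0792). Of 19 estrogen receptor targets 4 fell and 0 rose (5 fell adjusted over the list alone), with MYBL1 at -2.06 (SE 0.35) and EGR3 at -1.97 (SE 0.18). That list was shifted down (adjusted p = 0.00167, and adjusted p = 0.496 with an estimated correlation). All 18 interferon-stimulated genes had a negative difference with a median of -2.22, but 0 passed over all genes or adjusted over the list alone (list adjusted p = 0.00167, adjusted p = 0.924 with an estimated correlation, and 0.138 without first-generation array 1). The count of 1795 genes was 342 without wild-type array 1, 350 without wild-type array 2 and 1040 without either visceral metastases array. Of the 20 genes named by rule, MGP, NELL2, FABP5, ANXA1, CCN2 and CYP1A1 lost their calls without a wild-type array, with adjusted p between 0.0519 (CYP1A1, without wild-type array 1) and 0.134 (CCN2, without wild-type array 2). CCN2 also lost its call without first-generation array 1 (0.0549) or array 2 (0.0721).

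The RAF1-transfected and first-generation comparisons shared 285 higher and 473 lower genes, and 185 genes moved in opposite directions. Independent lists would share 121 and 140 genes, and simulated unchanged groups that shared the wild-type arrays gave 0 and 0.02. Almost no gene was called in those simulations, so their counts cannot show how far the shared arrays add to the overlap. The 2 wild-type arrays served both comparisons, and splitting them, which would leave 1 per comparison, was not done. The covariance of the log2 differences was 0.138, against 0.0337 in the simulated groups. Their correlation was 0.324, against 0.50 in the simulated groups, and 58.7% of genes had the same sign, against 66.7%. In unchanged groups the shared arrays alone set these 2 simulated values. Lying below them thus does not show how alike the comparisons were. The simulations gave each gene the same spread in all groups. The wild-type pair was closer than most (0.157), so the simulated covariance may be too high a baseline here.

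The RAF1 first-generation array was compared with RAF1 transfected, as the matching comparison among groups with the RAF1 label, with the spread taken from the other groups. The gene count was 5, all higher, at an adjusted p of 0.05 in limma, against 1474 genes at an unadjusted p under 0.05. PYCARD stood at 8.34 against 4.40 ± 0.09 (SD, n = 2), a log2 difference of 3.94 (SE 0.28, adjusted p = 0.00343). AZGP1, a secreted zinc-binding glycoprotein gene, rose by 2.91 (SE 0.21), the netrin gene NTN4 by 2.78 (SE 0.20), the extracellular protease gene ADAMTS15 by 1.99 (SE 0.20) and BEND7 by 1.75 (SE 0.19). The other BEND7 probe set past the filter had a difference of -0.32. No list was called, and the smallest adjusted p was that of cholesterol synthesis genes (0.0977, median -0.59). The count was 0 with only the arrays of both groups in the fit. It was 3 without either wild-type or either visceral metastases array, 9 without either first-generation array, 15 without RAF1 transfected array 2 and 74 without either lung metastases array. ADAMTS15 (adjusted p up to 0.121) and BEND7 (up to 0.121) lost their calls without either visceral metastases array, without either wild-type array or without RAF1 transfected array 1, and BEND7 also without either first-generation array (0.0512) or RAF1 transfected array 2 (0.0732).

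The RAF1 first-generation array was also compared with the first-generation pair, for the RAF1 label within first-generation material. WDR72 stood at 11.78 against 3.61 ± 0.01 (SD, n = 2), a log2 difference of 8.18 (SE 0.19, adjusted p = 7.07e-07), and PLS3 rose by 7.39 (SE 0.19). TNFSF15, a TNF family cytokine gene, rose by 6.24 (SE 1.01), the anthrax toxin receptor gene ANTXR1 by 5.28 (SE 0.26) and the epithelial transcription factor gene EHF by 5.28 (SE 0.27). The doublecortin-like kinase gene DCLK1 changed by -6.22 (SE 0.16), CA2 by -6.20 (SE 0.46), DMD by -6.11 (SE 0.51), PLAT by -5.65 (SE 0.15) and the monoamine oxidase gene MAOB by -5.40 (SE 0.30). In limma, 3418 of 14753 genes changed, 1883 higher and 1535 lower, and 1783 by at least 2-fold. With each array centred on its median the majority turned, with 1541 higher and 1773 lower. Of the 5 ANTXR1 probe sets past the filter, 4 had the same sign.

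Of 12 cholesterol synthesis genes, 7 fell and 0 rose between RAF1 first generation and first generation, and 10 fell when adjusted over the list alone, with MVD at -2.59 (SE 0.56), LSS at -2.55 (SE 0.40) and MSMO1 at -2.23 (SE 0.58). The list was shifted down by a median of -1.98 (adjusted p = 5.47e-05, and adjusted p = 0.8 with an estimated correlation). Of 23 cell cycle genes 6 rose and 0 fell (9 rose adjusted over the list alone), TOP2A by 2.66 (SE 0.77), with a list median of 1.20 (adjusted p = 0.000437, and adjusted p = 0.8 with an estimated correlation). The median value of this list was 10.22 on RAF1 first generation, 9.79 on first-generation array 1 and 8.34 on array 2. Without array 2 its adjusted p was 0.0106. Of 10 mammary stem cell markers 5 fell and 0 rose, also when adjusted over the list alone, with the drug transporter gene ABCG2 at -3.06 (SE 0.55), PROCR at -2.11 (SE 0.60), CD44 at -1.65 (SE 0.15) and SOX2 at -1.13 (SE 0.20). The stem cell list was shifted down (adjusted p = 0.0218, and adjusted p = 0.545 with an estimated correlation). ERK pathway transcripts were not called as a list (adjusted p = 0.639), with 5 of 20 higher and 2 lower (6 and 2 adjusted over the list alone). EGR1 at 3.17 (SE 0.66), MYC at 2.01 (SE 0.47) and SPRED1 at 1.56 (SE 0.24) were among the higher. The count of 3418 genes was 646 with only the arrays of both groups in the fit. BTBD6, at -5.45 (SE 1.39), lost its call without either first-generation array (adjusted p = 0.0534 and 0.0721) or either wild-type array (0.0502).

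**Figure D4:**
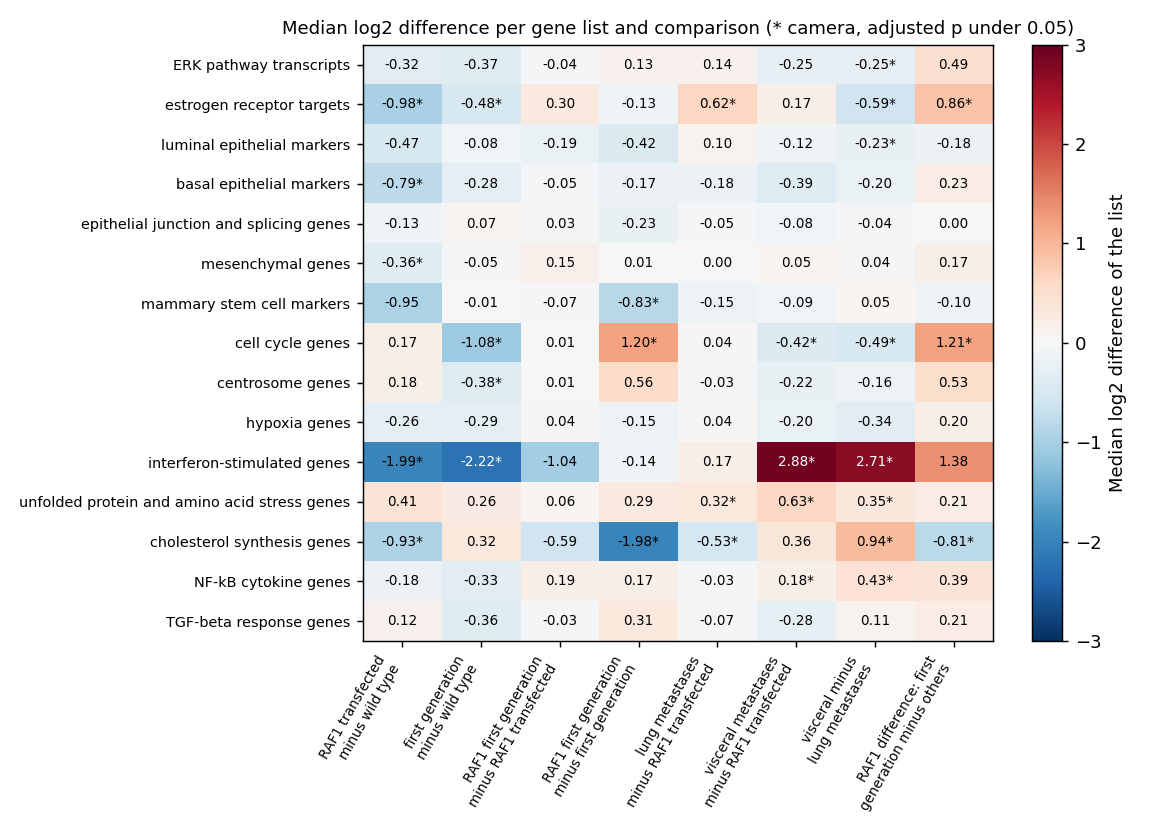
Median log2 difference of the measured members of 15 gene lists (vertical axis) in the 8 comparisons (horizontal axis), with an asterisk where camera gave an adjusted p under 0.05. Interferon-stimulated genes had the lowest (-2.22) and the highest (2.88) medians, and 0 list calls were left with an estimated correlation.

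The difference between groups with and without the RAF1 label was itself compared between first-generation material and the groups not called first generation. In limma, 515 genes passed this test, 341 with a higher and 174 with a lower difference in first-generation material, against 272 and 227 with each array centred on its median. MGP changed by -5.67 with the RAF1 label in the groups not called first generation and by 3.03 in first-generation material, a difference of 8.69 (SE 1.28, adjusted p = 0.0135). For the lipid chaperone gene FABP5 the effects were -1.11 and 3.89 (difference 5.00, SE 0.98), and for BLACAT1 they were -2.52 and 2.97 (difference 5.49, SE 0.66). For DMD they were -0.09 and -6.11 (difference -6.01, SE 0.66), for the xenobiotic enzyme gene CYP1A1 2.10 and -3.81 (difference -5.91, SE 0.82), and for FAT1 4.62 and -0.53 (difference -5.16, SE 0.49). CT83 (difference 6.10, SE 0.20) was at 10.25 ± 0.07 in wild type (SD, n = 2) and between 3.83 and 4.01 in the group means of the 5 other groups. CT83 in both first-generation groups, and DMD in wild type and RAF1 transfected, lay under 5, where a fall could not be seen. BLACAT1 lay under 5 in first generation and RAF1 transfected, FAT1 in wild type and FABP5 on first-generation array 2 (4.51). The sizes of these differences thus depend on the floor of the signal. The effect in first-generation material rests on the lone RAF1 first-generation array, whose faults could pass as a difference.

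Estrogen receptor targets were shifted up in this test of the difference, with 4 of 19 higher and 0 lower (6 higher adjusted over the list alone), PDZK1 at 5.59 (SE 0.35), MYBL1 at 3.11 (SE 0.55) and PGR at 1.87 (SE 0.39) among them (adjusted p = 0.000457, and adjusted p = 0.403 with an estimated correlation). Cell cycle genes were shifted up, with 1 of 23 past the test (6 adjusted over the list alone) and a median of 1.21 (adjusted p = 0.000457, and adjusted p = 0.952 with an estimated correlation). Cholesterol synthesis genes were shifted down with 0 of 12 past the test over all genes or adjusted over the list alone (adjusted p = 0.0327, and adjusted p = 0.952 with an estimated correlation). The cell cycle call ended without first-generation array 2 (adjusted p = 0.419), and the cholesterol call without first-generation array 1 (0.559) or RAF1 transfected array 1 (0.33). The count of 515 was 119 and 107 without wild-type array 1 and 2, 185 without either visceral metastases array, 830 without either lung metastases array, 917 without first-generation array 1 and 318 with only the 4 groups compared. Without a wild-type array MGP (adjusted p up to 0.0738), FABP5 (up to 0.143), CYP1A1 (0.0596), GJA1 (0.066) and AGTR1 (0.057) lost their calls, and FABP5 also without RAF1 transfected array 1 (0.0581) or array 2 (0.0718) or either visceral metastases array (0.0835).

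Lung metastases were compared with RAF1 transfected to ask what set them apart from that group. The labels do not name the cells that gave the metastases. Against wild type and first generation, lung metastases differed in 4353 and 4740 genes in limma, so their values lay far closer to RAF1 transfected than to those groups. They lay close to RAF1 first generation too. The Pearson correlation across genes with that array was 0.981 for lung metastases array 1 and 0.983 for array 2. With RAF1 transfected arrays 1 and 2 it was 0.967 and 0.978 for lung metastases array 1, and 0.992 and 0.981 for array 2. A single gene, PYCARD, changed in limma at an adjusted p of 0.05, against 876 genes at an unadjusted p under 0.05. PYCARD rose from 4.40 ± 0.09 to 8.99 ± 0.58 (SD, n = 2 each), a log2 difference of 4.59 (SE 0.23, adjusted p = 0.000508), close to its level of 9.71 ± 0.02 in wild type. On the RAF1 first-generation array PYCARD was 8.34. The gene had 1 probe set, whose suffix marks sequence shared between transcripts, and the count was 0 with only the arrays of both groups in the fit. It was also 0 with only probe sets without such suffixes, which leaves PYCARD out. The number of changed genes was 2 without lung metastases array 1, 235 without lung metastases array 2, 8 without RAF1 transfected array 1 and 3 without either first-generation array.

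Estrogen receptor targets were shifted up in lung metastases, 18 of 19 with a positive difference and a median of 0.62, although 0 passed over all genes and 7 when adjusted over the list alone (camera, adjusted p = 7.36e-12, and adjusted p = 0.0749 with an estimated correlation). The progesterone receptor gene PGR, an estrogen-induced gene, had values of 11.61 and 11.34 in lung metastases against 9.89 and 9.48 in RAF1 transfected, and PDZK1 had a difference of 1.89 (SE 0.22, adjusted p = 0.0849). Unfolded protein and amino acid stress genes were shifted up, 13 of 14 with a positive difference, a median of 0.32 and 0 past the test over all genes or adjusted over the list alone (adjusted p = 0.00868, and adjusted p = 0.924 with an estimated correlation). Cholesterol synthesis genes were shifted down, all 12 with a negative difference, a median of -0.53 and 0 past either test (adjusted p = 0.000452, and adjusted p = 0.924 with an estimated correlation). The stress list call ended without lung metastases array 1 (0.873) or RAF1 transfected array 1 (0.29), and the cholesterol call without the same arrays (0.36 and 0.777). Of 10 lung epithelial markers 0 changed, and that list was not called (smallest adjusted p over the 8 comparisons 0.446). Lung tissue of a host mouse was not tested by this list of human genes. With 1 of 14753 genes past the threshold here, 0 of 10 carries little weight.

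Visceral metastases were compared with RAF1 transfected for the same question. TM4SF1 fell from 11.55 ± 0.20 to 5.10 ± 0.02 (SD, n = 2 each), a log2 difference of -6.46 (SE 0.71, adjusted p = 0.0149), and was 5.09 ± 0.03 in wild type. The vitamin B12 binder gene TCN1 rose by 3.53 (SE 0.28), the mitochondrial folate enzyme gene ALDH1L2 by 3.36 (SE 0.31), the nuclear envelope gene SYNE1 by 2.93 (SE 0.14) and the growth factor gene TGFB2 by 2.39 (SE 0.23). The interferon-inducible genes TRIM22, RSAD2 and PSMB9 rose by 2.82 (SE 0.29), 2.81 (SE 0.48) and 2.53 (SE 0.43). In limma, 139 of 14753 genes changed, 71 higher and 68 lower, against 111 and 51 with each array centred on its median, and 70 changed by at least 2-fold.

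All 18 interferon-stimulated genes had a positive difference between visceral metastases and RAF1 transfected, with a median of 2.88, but 0 passed over all genes or adjusted over the list alone (list adjusted p = 1.78e-08, and adjusted p = 0.843 with an estimated correlation). The list medians were 10.59 on both visceral arrays against 6.04 and 9.65 on RAF1 transfected arrays 1 and 2. Of 14 unfolded protein and amino acid stress genes 1 rose, SESN2 by 1.58 (SE 0.25), and 5 when adjusted over the list alone. The list was shifted up (adjusted p = 2.7e-05, and adjusted p = 0.69 with an estimated correlation). Of 10 NF-kB cytokine genes 2 rose, also when adjusted over the list alone, RELB by 1.04 (SE 0.14) and TNFAIP3 by 0.91 (SE 0.15). That list was shifted up (adjusted p = 0.00453, and adjusted p = 0.384 with an estimated correlation). Cell cycle genes were shifted down with 0 of 23 past the test and 3 adjusted over the list alone (adjusted p = 0.0272, and adjusted p = 0.851 with an estimated correlation). This call ended without RAF1 transfected array 1 (0.104) or array 2 (0.0716) or visceral array 2 (0.0692). The count of 139 genes was 3 without either visceral array, 14 without either wild-type array, 89 without RAF1 transfected array 1 and 24 with only the arrays of both groups. It was 234 without either first-generation array and 343 without either lung metastases array. Of the 20 genes named by rule, SYNE1 alone kept its call without each array in turn. TM4SF1 lost its call without either visceral array (adjusted p = 0.195 and 0.188) or either wild-type array (0.0653).

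**Figure D5:**
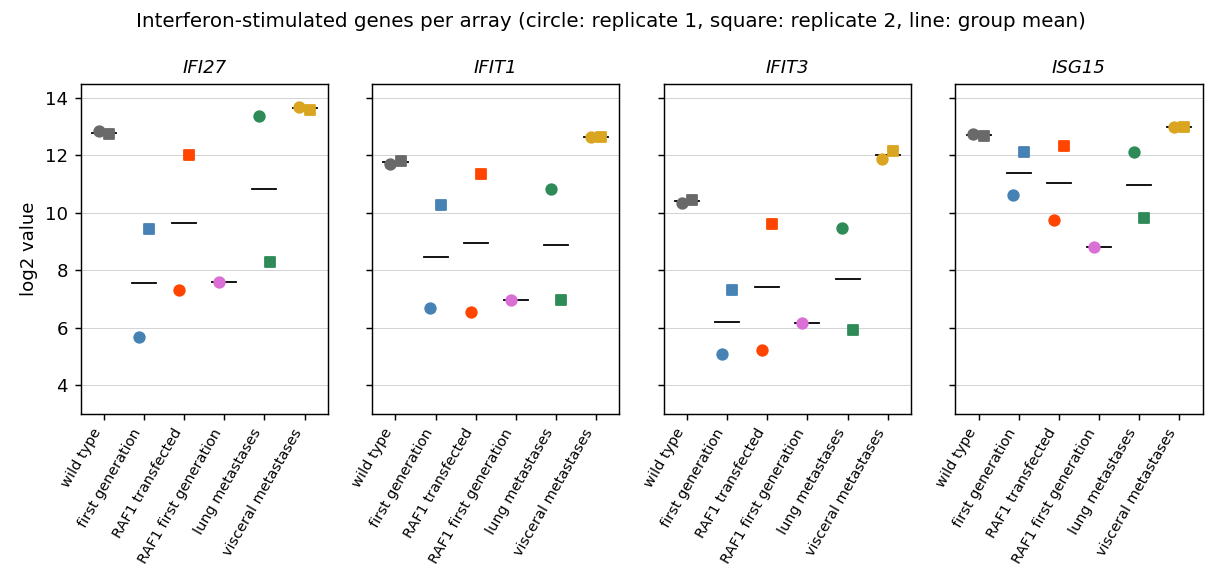
Log2 values of 4 interferon-stimulated genes on each array, by group, with the group mean as a line. The values of a pair lay close together in wild type and visceral metastases and far apart in first generation, RAF1 transfected and lung metastases, where IFIT1 was at 6.53 and 11.35 on the RAF1 transfected arrays and at 10.81 and 6.98 on the lung metastases arrays.

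Visceral and lung metastases were compared directly. TM4SF1 changed by -6.52 (SE 0.71, adjusted p = 0.00792) and PYCARD by -4.55 (SE 0.23, adjusted p = 0.000272), which left both near 5 or below in visceral metastases. ANTXR1 changed by -2.44 (SE 0.21) and ADAMTS15 by -2.42 (SE 0.16), while ALDH1L2 rose by 3.84 (SE 0.31), FGF13 by 3.65 (SE 0.42), TGFB2 by 3.25 (SE 0.23) and CYP1A1 by 2.95 (SE 0.52). In limma, 314 genes changed, 128 higher and 186 lower, against 189 and 123 with each array centred on its median. Of the 5 ANTXR1 probe sets past the filter, 3 had the same sign.

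Estrogen receptor targets were shifted down in visceral against lung metastases, with 2 of 19 lower, PGR at -1.34 (SE 0.25) among them, 6 lower adjusted over the list alone, and 0 higher (adjusted p = 0.000616, and adjusted p = 0.238 with an estimated correlation). Luminal markers were shifted down with 1 of 15 lower, MUC1 at -1.06 (SE 0.20), and 1 higher and 5 lower adjusted over the list alone (adjusted p = 0.0253, and adjusted p = 0.238 with an estimated correlation). ERK pathway transcripts were shifted down with 1 of 20 lower, also when adjusted over the list alone, IER3 at -1.06 (SE 0.15) (adjusted p = 0.0169, and adjusted p = 0.238 with an estimated correlation). NF-kB cytokine genes were shifted up with 1 of 10 higher, RELB at 1.12 (SE 0.14), and 4 adjusted over the list alone (adjusted p = 0.000683, and adjusted p = 0.238 with an estimated correlation). Cholesterol synthesis genes were shifted up, all 12 with a positive difference and a median of 0.94, with 0 past the test and 3 adjusted over the list alone (adjusted p = 0.000113, and adjusted p = 0.893 with an estimated correlation).

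Interferon-stimulated genes were shifted up between visceral and lung metastases with 0 of 18 past either test (adjusted p = 1.26e-06, and adjusted p = 0.893 with an estimated correlation), as were stress genes with 0 of 14 past the test and 1 adjusted over the list alone (adjusted p = 0.0253, and adjusted p = 0.934 with an estimated correlation). The interferon list medians were 9.42 and 6.62 on lung metastases arrays 1 and 2 against 10.59 on both visceral arrays, and without lung metastases array 2 the adjusted p of that list was 0.0387. Cell cycle genes were shifted down with 0 of 23 past either test (adjusted p = 0.0169, and adjusted p = 0.952 with an estimated correlation). Without lung metastases array 2 the calls of the ERK list (0.106), the cell cycle list (0.307) and the stress list (0.627) ended, as did the luminal call without lung metastases array 1 (0.166) and the stress call without either first-generation array (0.0526). The count of 314 genes was 3 and 4 without visceral array 1 and 2, 57 without either wild-type array and 95 with only the arrays of both groups. It was 595 without lung metastases array 2, 574 without either first-generation array and 494 without either RAF1 transfected array. Of the 20 genes named by rule, SYNE1, PYCARD and ADAMTS15 kept their calls without each array in turn. TM4SF1 lost its call without visceral array 1 (adjusted p = 0.11) or array 2 (0.0965).

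The lung and visceral comparisons shared 0 genes in either direction, where independent lists of these sizes would share 0.00481 higher genes and simulated unchanged groups gave 0. In limma the lung comparison had 1 gene to share. The covariance of their log2 differences was 0.0205, against 0.0339 in simulated unchanged groups that shared the RAF1 transfected arrays. Their correlation was 0.187, against 0.502, and 58.0% of genes had the same sign, against 66.7%. As above, the shared arrays alone set the last 2 simulated values, so lying below them does not show how alike the comparisons were. The RAF1 transfected pair lay further apart (0.431) than the wild-type and visceral pairs, so the simulated covariance may be too low a baseline here. The 2 RAF1 transfected arrays served both comparisons and were not split between them.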

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

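The tests of explanations in this part were chosen only after the result was seen, except the one on chromosome segments.

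By a test of the difference itself, 515 genes differed between first-generation material and the other groups in the effect of the RAF1 label, and 314 genes differed between visceral and lung metastases, each set against RAF1 transfected. Among the 515, the effect was higher in first-generation material by 8.69 on the log2 scale for MGP, 6.10 for CT83, 5.59 for PDZK1, 5.49 for BLACAT1 and 5.00 for FABP5. It was lower there, with differences of -6.01 for DMD, -5.91 for CYP1A1, -5.55 for GJA1, -5.16 for FAT1 and -4.92 for AGTR1. The RAF1 first-generation arm was 1 array, so a fault of that array could pass as a difference in effect. CT83 lay under 5 in both first-generation groups, and DMD, GJA1 and AGTR1 lay under 5 in wild type and RAF1 transfected. A fall with the label could not be seen there. BLACAT1 lay under 5 in first generation and RAF1 transfected, and FAT1 in wild type. The sizes of these 6 differences thus depend on the floor of the signal, and FABP5 was also under 5 on first-generation array 2 (4.51). The count of 515 was 107 without wild-type array 2 and that of 314 was 3 without visceral array 1. No explanation was tested for these differences, and the growth conditions that the group names imply stay among the open ones.

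Interferon-stimulated genes differed within pairs of the same group: array 2 minus array 1 had a list median of 3.69 in RAF1 transfected, with 18 of 18 genes higher, and of -2.68 in lung metastases, with 0 of 18 higher. It was 1.32 in first generation, again with 18 of 18 higher. The amount of labelled RNA is argued against, since the wild-type arrays differed by 1.37 in the poly-A spike controls, against -0.46 in RAF1 transfected, and yet by a median of only 0.116 in size in these genes. The lung metastases arrays differed by 1.62 in the spike controls, the first-generation arrays by -0.29, and in all 3 shifted pairs the spike difference had the opposite sign to the interferon shift, so the argument rests on the wild-type pair and on the visceral pair (0.63 in the spike controls and a list median of 0.01). RNA degradation is argued against too, since array 2 had the larger 3 prime minus 5 prime ACTB difference in both pairs (by 0.31 and 0.25) while the interferon shift was 3.69 in one and -2.68 in the other. An exchange of labels between 1 RAF1 transfected and 1 lung metastases array cannot be told apart from a difference between samples of 1 group, and would leave the shift within first generation unexplained. Outside the interferon list, 14 genes separated the pairs as labelled by a gap over 1 on the log2 scale, PYCARD by 4.12, and 106 separated the pairs made by the exchange. The 106 partly restate the interferon shift, since they hold interferon-inducible genes that the list lacks, such as SAMD9, DDX60 and IFITM1. They also hold genes of other kinds, such as CAV1 (gap 3.06), COL12A1 (2.57) and EFEMP1 (2.32), so that shift does not account for all of them. The counts do not decide, since a difference between samples of 1 group could bring such gaps too. An exchange would alter every comparison with these 2 groups. A biological difference between cultures or animals may exist and was not tested.

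PYCARD was 4.40 in RAF1 transfected and 4.44 in visceral metastases, but 8.99 in lung metastases and 8.34 in RAF1 first generation. Cells without the RAF1 construct in the lung samples are argued against as the source. Their share would need to be 59.5%, and the 32 genes at least 16-fold lower in RAF1 transfected than in wild type would then rise by a median of 4.08, but they rose by 0.116 (upper quartile 0.435). The upper quartile of the rise thus lay far below the median rise needed. Sequence shared with other transcripts was not tested for the single PYCARD probe set. The high level was not particular to lung metastases. PYCARD was also high on the lone RAF1 first-generation array (8.34), on the wild-type arrays (9.73 and 9.70) and on the first-generation arrays (10.03 and 10.05). These values argue against a level found at the lung site alone. Whether the site raised PYCARD from a level as low as that in RAF1 transfected was not tested.

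The split between RAF1 transfected and wild type held 4292 changed genes. Long gained or lost chromosome segments are argued against as the whole cause: after the median of 51 neighbouring genes was removed, 3882 genes changed. That was against 4294 before, among the 14731 genes with a known neighbour order. Segments much shorter than 51 genes would escape this correction. Of these genes, 1540 had a neighbourhood median over 0.3 in size on the log2 scale (largest 0.75), so segments as a part of the cause stay open. RNA degradation is argued against, since the 3 prime minus 5 prime ACTB differences overlapped. They ran from 0.28 to 0.60 over 3 arrays with the RAF1 label and from 0.27 to 0.60 over 4 wild-type and first-generation arrays. The metastasis arrays, whose labels do not name RAF1, were not in this comparison. Whether higher ERK output underlies the split cannot be told apart from other effects of the construct or of clonal growth, since the ERK list had a median of -0.32 with quartiles of -0.76 and 0.23 and members that went both ways. The level of RAF1 was not analysed here.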

How the results depend on the processing

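The range of alternatives was set before the data were examined, and no alternative was added later. No named gene reversed, and no list call did under the settings run for lists: no filter, quantile normalization, the mean over probe sets, the estimated correlation, fry and left-out arrays. List calls were not tested under the other settings. Among named genes, 1075 calls were kept and 55 were lost over the settings other than left-out arrays, and 1064 were kept and 177 lost without 1 array. Among list calls these were 99 and 51, and 292 and 32. The counts rest on 2 arrays per group, or 1 for RAF1 first generation. They also rest on a shared spread, to which the pairs of wild-type and visceral arrays (0.157 and 0.149) added the least. No paired analysis was possible because the labels pair no arrays. Each other RAF1 probe set, an alternative for the RAF1 level, was not run.

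RAF1 first generation minus RAF1 transfected gave 11 genes with no filter, 3 with a filter at 7, 3 with the mean over probe sets, 8 with a trend and robust prior, 29 with array weights (23 higher and 6 lower) and 0 with only the arrays compared. Lung metastases minus RAF1 transfected gave 4 genes with centred arrays. Visceral metastases minus RAF1 transfected gave 80 genes with the mean over probe sets, 64 with only probe sets without shared-sequence suffixes, 24 with only the arrays compared (20 higher and 4 lower) and 628 with array weights. With only the arrays compared, RAF1 first generation minus first generation gave 646 genes, visceral minus lung metastases 95 and the difference between RAF1 effects 318. With array weights the last 2 gave 593 and 912. The fold threshold left 1586 genes for RAF1 transfected minus wild type, 687 for first generation minus wild type (228 higher and 459 lower), 1783 for RAF1 first generation minus first generation, 70 for visceral metastases minus RAF1 transfected and 166 for visceral minus lung metastases, fewer by construction. Against wild type and first generation as references, lung metastases gave 4353 and 4740 genes and visceral metastases 4861 and 5292. Against RAF1 first generation they gave 1 gene, which was lower, and 100 genes (42 higher and 58 lower). With the estimated correlation 0 of the 30 list calls were left, and fry called 37 pairs, 13 of the 30 among them. For the settings other than the fold threshold and the reference groups, the cause was not tested.

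Without 1 array, the counts ranged from 1793 to 4903 for RAF1 transfected minus wild type, from 342 to 2188 for first generation minus wild type, from 3 to 74 for RAF1 first generation minus RAF1 transfected, from 2451 to 3915 for RAF1 first generation minus first generation, from 1 to 235 for lung metastases minus RAF1 transfected, from 3 to 343 for visceral metastases minus RAF1 transfected, from 3 to 595 for visceral minus lung metastases, from 107 to 917 for the difference between RAF1 effects, and from 24 to 32 for list calls. Leaving out an array of a group outside a comparison does not change the log2 differences of that comparison. It changes only the shared estimate of the spread and its degrees of freedom. For arrays of the groups compared, the share of each cause was not tested.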

Other observations

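No test of an explanation was run for this part, and BTBD6, SYNPO2 and MGP were chosen for their values on single arrays after these were seen.

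For 3 other lists no comparison gave a list call, and some members changed. Of all genes tested, 29.1% changed in RAF1 transfected against wild type and 23.2% in RAF1 first generation against first generation. Of 19 epithelial junction and splicing genes, 4 fell and 1 rose in RAF1 transfected against wild type, also when adjusted over the list alone, with the transcription factor gene OVOL2 at 1.60 (SE 0.25) and the polarity gene LLGL2 at -1.26 (SE 0.17). This list had its smallest adjusted p over the 8 comparisons at 0.085 (RAF1 first generation minus first generation). Of 15 hypoxia genes, 3 fell and 1 rose in RAF1 transfected against wild type, also when adjusted over the list alone, the glycolytic enzyme gene PGK1 at -1.09 (SE 0.18) and VEGFA at 0.80 (SE 0.21), and the smallest adjusted p of that list was 0.086. Of 12 TGF-beta response genes, 4 rose and 2 fell in RAF1 first generation against first generation (4 and 3 adjusted over the list alone), with TGIF1 at 1.95 (SE 0.18) and ID3 at -1.78 (SE 0.31), and the smallest adjusted p was 0.644.

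Lung metastases array 2 lay nearer to RAF1 transfected array 1 than either lay to the other array of its group. The Pearson correlation across genes, which are not independent replicates, was 0.992 for that pair, 0.974 within lung metastases and 0.978 within RAF1 transfected. BTBD6 was 4.72 on lung metastases array 1 and 4.75 on RAF1 first generation, and between 9.21 and 10.29 on the 9 other arrays. SYNPO2 was 9.61 on lung metastases array 1 and 4.04 on array 2. MGP was 11.11 and 8.37 on the lung metastases arrays.

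Markers of other cell types gave 0 list calls in the 8 comparisons. The smallest adjusted p was 0.0664 for fibroblast and matrix markers (9 measured), 0.725 for endothelial (10), 0.24 for macrophage and leukocyte (6), 0.446 for lung epithelial (10), 0.24 for hepatocyte (10), 0.654 for gut, pancreas and kidney epithelial (8), 0.333 for mesothelial (2), 0.679 for erythroid (4), 0.387 for skeletal muscle (4) and 0.679 for adipocyte markers (4). Single members did change, such as SERPINA1 of the hepatocyte list at -3.49 (SE 0.46) and UPK3B of the mesothelial list at -2.07 (SE 0.16), both in RAF1 transfected against wild type. No list of mouse transcripts was used, so these lists do not test for tissue of the host mice.

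Genes that neighbour each other moved alike in each of 7 comparisons between groups. The rank correlation of the log2 differences of neighbouring genes was between 0.10 and 0.21, and none of 1000 shuffles of gene order reached the observed value (permutation p = 0.001, the smallest that 1000 shuffles allow).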
